A study of Mus musculus with 2 samples.

How the data were processed

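Single cells from the bone marrow of 8-week-old C57BL/6 mice carrying the Fucci cell cycle reporter were profiled by RNA sequencing. In Fucci mice the orange protein mKO2 is fused to a fragment of Cdt1 and marks G0 and G1 cells, and the green protein mAG is fused to a fragment of geminin (Gmnn) and marks S, G2 and M cells. Per the labels' protocols, cells were processed with a modified Smart-seq2 method in which the 3' ends of the amplified cDNA were enriched with biotin and streptavidin beads. One library held the mKO2neg and mAG+ gates and the other the mKO2high and mKO2low gates, with 48 cells in each of the 4 gates. The deposited cell table gave the library and gate of all 192 cells, the same number as the study states.

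The deposited values were whole-number counts per gene row and cell, and no normalization had been applied to these counts. HISAT2, HTSeq 0.11.3 and Seurat, and the mouse genome build mm10, are named in the submitters' processing notes, without a role or order. The annotation release, the filters and whether molecular identifiers were used are not given in the sources used here. Each table had 53378 gene rows, each with a versioned Ensembl ID and a symbol. By gene ID, 53273 of these were found in GENCODE M21 (GRCm38, the same assembly as mm10), which supplied gene types and coordinates, and 105 rows holding 0.222% of the counts were not. All columns of cells were used.

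Symbols are those the deposited tables pair with each ID, and a gene is named as "the row labelled" with its symbol, because the labels and the counts were at odds. Rows labelled with genes that nearly every cell transcribes held almost no counts, as the report describes. The closing section tests a displacement of the labels by 1 gene. No row was given another name on that account, so a value printed here belongs to the row that carries the label and cannot be read as the expression of that gene. For the same reason gene functions are given for a few labels as background and are not read into the values, and the members of gene lists are summarised and not listed.

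Counts were summed over the cells of a gate and scaled to the gate's total as CPM. A log2 ratio of 2 gates used a prior count of 1, scaled to the gate's total, and rows with at least 10 counts over both gates entered the lists. Intervals are exact conditional binomial 95% intervals for single rows, and for a list's median the central 95% of medians over Poisson draws of its counts. Shares of cells have exact Clopper-Pearson 95% intervals. Without molecular identifiers known to be used, reads are not independent molecules, and intervals cover counting error only. The floor for a row with no count was 3 counts over the gate, which is 3.21 CPM in mKO2high, 1.76 in mKO2low, 1.86 in mKO2neg and 1.07 in mAG+. A fold given at the floor divides the other gate's CPM by it. Such a fold leaves out counting error in that other gate, so it can exceed the interval's lower limit. The sources name no animals or cultures, so each gate is 1 sample, cells were not treated as replicates and no test was run. A list's median was set beside 10000 random lists of the same size matched on mean expression, as a description of these libraries. With labels and counts at odds, this percentile describes the labelled rows and is no support for the biology a list is named for. It was not computed for the alternatives.

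All comparisons, gene lists and the rule for named rows were fixed before the data were examined. The rule took, within each library, the 10 rows with the largest log2 ratio in each direction among those with a count in at least 12 cells of the higher gate, with at most 25% of the gate's summed per-cell CPM in any 1 cell, and with the same direction in the mean of per-cell CPM. It also named 22 genes of the cell cycle and of stem and progenitor cells, whatever their number of cells, and up to 4 members of each of 31 gene lists. Beyond the S phase, G2/M and stem cell lists, the lists reported for a comparison are a selection. Their medians lie toward either end of the matched random lists, and among 31 lists some such medians arise without any difference. One listed symbol, Cd244a, was not among the deposited labels. Some rows that the rule names are not reported here. For cell depth, every cell was also thinned to 5000 counts, leaving out 9, 0, 5 and 3 shallower cells of mKO2high, mKO2low, mKO2neg and mAG+. The filter of at least 10 counts was applied again after thinning. A list's median at equal depth therefore covers fewer rows than the reported one, and a changed median need not mean that the same rows changed. No intervals are given for ratios at equal depth, and a row left without counts in either gate is at 0. Doublets were not called, since cells were sorted or transferred singly.

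The alternatives were edgeR's TMM factors, DESeq2's size factors, equal weight for each cell, only cells with at least 1000 gene rows and under 20% of counts in mitochondrially encoded rows, thinned cells, no filter on low counts, a prior count of 5, the cell with most counts left out per row and gate, and mitochondrial counts left out of the total. Equal weight kept every cell with a count, including cells with as few as 1 count in mKO2neg and 2 in mKO2high. A count in such a cell weighs far more than a count in a deep cell, which limits the values with equal weight. Chosen after the data were seen were the counts of the preceding gene in the annotation's order, for whole lists only, and leaving out the deepest cell of each gate. The calculation was tested on simulated counts in which 200 rows had been changed. The gate sums were Poisson draws from pooled means, the model the intervals assume, without spread between cells. The shares below therefore check the calculation and do not give its power in these data. For mAG+ against mKO2neg, with 12137 rows, 83.6% of the rows changed 2-fold and 91.0% of those changed 4-fold had an interval excluding 0 in the right direction, as did 87.9% of those changed 8-fold. For mKO2low against mKO2high, with 10921 rows, the shares were 73.1%, 88.1% and 92.4%. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.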

Results

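The data were counts from 192 sorted bone marrow cells of the Fucci reporter mouse, 48 in each of 4 gates, in a study of quiescent blood stem cells. The library of mKO2neg and mAG+ cells held 4400214 counts and that of mKO2high and mKO2low cells 2637299. Summed counts were 934036 in mKO2high, 1703263 in mKO2low, 1608630 in mKO2neg and 2791584 in mAG+. Single cells ranged from 0 to 83162 counts in mKO2high, from 7436 to 117134 in mKO2low, from 1 to 210516 in mKO2neg and from 315 to 184672 in mAG+. Each gate is 1 sample without replicates, so the values below have no replicate check.

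The deposited gene labels were at odds with the counts, and this limits every value given by name. Of 7037513 counts, the row labelled Actb, the gene of beta-actin, held 136, and the row labelled Gapdh, a glycolytic enzyme, held 799. No count lay in the rows labelled Malat1, B2m, Eef1a1, Rpl13, mt-Co1 or Kit, although each of the first 5 is among the abundant transcripts of most mouse cells. The 83 rows labelled with ribosomal protein genes together held 0.167% of the counts. Rows with many counts instead included that labelled mt-Tv, a mitochondrial tRNA gene, with 106805 counts. The row labelled Patl2 held 56396. Rows labelled with small nuclear RNA genes were also among the top, such as Gm24499 with 43138 counts. Of the 22 genes fixed in advance, 8 had no count in any cell under their label: Ccnd1, Ccnd2, Cdkn1a, Cdkn1c, Procr, Cd48, Kit and Ly6a. All names below are those of the deposited rows, and no statement on the named gene itself is made.

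The number of gene rows counted per cell does not depend on their names. It was highest in mAG+ cells, with a median of 4910 rows, against 3026 in mKO2neg, 3516 in mKO2low and 2546 in mKO2high. Median counts per cell were 45177 in mAG+, 24633 in mKO2neg, 26852 in mKO2low and 14510 in mKO2high. At an equal depth of 5000 counts, the medians were 2138 rows in 45 mAG+ cells, 1849 in 43 mKO2neg cells, 1888 in 48 mKO2low cells and 1794 in 39 mKO2high cells. The lower and upper quartiles of mAG+ cells were 2047 and 2180 rows at this depth, both above the upper quartiles of mKO2neg at 1933, mKO2low at 1984 and mKO2high at 1862. Mitochondrially encoded rows held a median of 3.34% of a cell's counts in mKO2high, 3.66% in mKO2low, 3.03% in mKO2neg and 3.32% in mAG+.

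**Figure D1:**
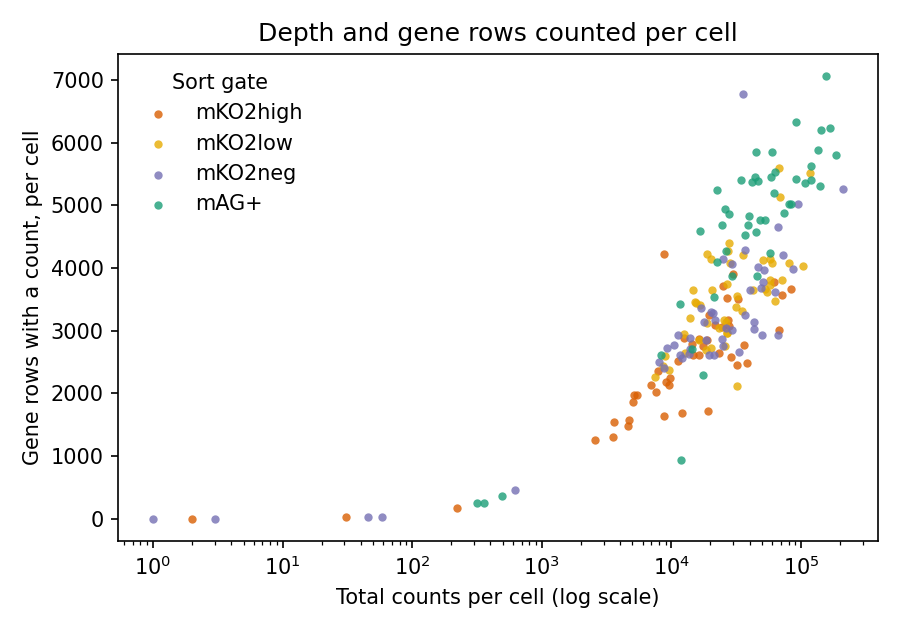
Gene rows with a count (vertical axis) against total counts on a log scale (horizontal axis) for each cell with a count, coloured by sort gate. Most mAG+ cells, with a median of 4910 rows, lie above most cells of the other gates at like depth.

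The first comparison within a library set mKO2low against mKO2high, the lower and higher levels of the G0 and G1 reporter. Higher in mKO2low was the row labelled Usp39, with 33 counts against 0. That is 6.03-fold higher at the floor, with a lower 95% limit of the log2 ratio of 2.21. The row labelled Prdm13 had a log2 ratio of 3.62 (95% interval 1.78 to 9.68). The rows labelled Gm25821, Ewsr1, Gm12016, Il6, Cdc37, Fut7, BC051226 and Psmb1 followed, with log2 ratios from 3.27 to 3.51, intervals above 0 and at most 3 counts in mKO2high. At equal depth per cell the row labelled Fut7 was at 0.00, the value of a row without counts in either gate. It therefore does not show that this difference was lost. The others higher in mKO2low were at 1.96 or above. Higher in mKO2high were rows labelled Gm25203, with a log2 ratio of -3.66 (-4.69 to -2.96), Capn7 at -3.02 (-4.13 to -2.27) and Dsn1 at -2.85 (-4.02 to -2.06), and at equal depth these were at -2.42, -1.94 and -2.11. The row labelled H2-Ab1 had 56.9 CPM in mKO2low and 234 in mKO2high, a log2 ratio of -2.03 (-2.40 to -1.69), which was -0.85 with equal weight for each cell. The rows labelled Gm15675, AC164123.1, Gm43786, Eaf2, Washc4 and Acad10 lay between -2.48 and -2.04, of which Gm15675 and Acad10 were at -0.75 and -0.76 at equal depth.

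Among rows labelled with genes fixed in advance, Hlf had 86.3 CPM in mKO2low and 270 in mKO2high (log2 ratio -1.64, -1.95 to -1.35), and Mecom had 9.98 and 32.1 CPM (-1.61, -2.64 to -0.78). At equal depth the row labelled Hlf was at -0.08 and that labelled Mecom at 0.41. Thinning keeps only part of the counts and no interval was computed, so these values do not show whether depth explains the differences. Before thinning, the row labelled Mecom had only 17 counts in 3 mKO2low cells and 30 in 5 mKO2high cells, too few for a direction at equal depth. The rows labelled with the reporter's genes differed less, with Cdt1 at -0.37 (-0.58 to -0.16) and Gmnn at -0.20 (-0.67 to 0.28). The row labelled Slamf1 was at 0.25 (-0.15 to 0.66). Of 20 measured rows with S phase labels, 13 were higher in mKO2low and 7 lower, with a median log2 ratio of 0.45 (0.13 to 0.71). The G2/M list had 10 of 17 rows higher and a median of 0.26 (-0.40 to 0.86), which was -0.03 both with equal weight for each cell and without the deepest cell of each gate. The stem cell list had 7 of 9 rows lower in mKO2low and a median of -0.75 (-1.27 to -0.21), below all but 1.93% of matched random lists. At equal depth per cell, over the rows that still had at least 10 counts, the S phase median was -0.15 and the stem cell median -0.07. Rows with oxidative phosphorylation labels had a median of 0.67 (0.41 to 0.84), with 15 of 20 higher in mKO2low, and those with interferon response labels 0.90 (0.50 to 1.44), with 6 of 8 higher, which was 0.16 at equal depth. Rows with immediate early labels were mixed, with 6 of 9 lower in mKO2low and a median of -0.72 (upper bound -0.40), but a mean of 0.12 and 3 rows at least 2-fold higher beside 3 at least 2-fold lower. Rows with p53 target labels had a median of -0.66 (-0.88 to -0.21), with 3 of 4 lower, but a mean of -0.13 and a summed CPM of 357 in mKO2low against 348 in mKO2high.

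The second comparison within a library set mAG+, the gate of the S, G2 and M reporter, against mKO2neg. The row labelled Mat2b had 275 CPM in mAG+, with counts in 43 of 48 cells, against 1.86 CPM and 3 cells in mKO2neg, a log2 ratio of 6.89 (5.65 to 9.49). The row labelled Gm11443 had 161 counts in mAG+ and 0 in mKO2neg, 30.9-fold higher at the floor (lower 95% limit of the log2 ratio 4.64). Those labelled Gm12309, Cutal and Kctd18 were 23.2-fold, 19.2-fold and 17.7-fold higher at the floor (lower limits 4.22, 3.94 and 3.82). The row labelled Gm15544 had 192 counts against 1 (6.01, 4.29 to 12.1). Rows labelled Gm43178, Gm45170, Gm43143 and Gm11667 had no count in mKO2neg. They were 15.6-fold, 14.8-fold, 14.6-fold and 12.1-fold higher at the floor (lower limits 3.63, 3.55, 3.53 and 3.26). At equal depth, with fewer counts beside the same prior count, the row labelled Mat2b was at 4.81, Gm15544 at 3.97, Gm11443 at 1.98, and the others of these rows between 2.30 and 3.14. Lower in mAG+ were rows labelled Platr7, with a log2 ratio of -4.71 (-6.29 to -3.86), Slc22a18 at -3.56 (-4.64 to -2.84), Gm44350 at -3.52 (-3.87 to -3.23) and Got1 at -3.30 (-3.95 to -2.79). The row labelled Stard7 had 43.3 CPM in mAG+ and 295 in mKO2neg (-2.76, -3.07 to -2.48). The rows labelled Samd14, Gm25654, Sh3tc2, Gm14169 and Gm25939 lay between -2.84 and -2.69. At equal depth those labelled Sh3tc2 and Gm25939 were at -1.25 and -1.56 and Samd14 at -2.22, while Gm44350, Gm14169 and Stard7 were at -4.16, -3.75 and -3.42 and Platr7 at -4.00.

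The row labelled Mki67, the gene of a protein of proliferating cells, had 4 counts in mAG+ and 0 in mKO2neg. These are too few for a difference to be detectable in this row. With labels and counts at odds, they do not show whether the gene itself was expressed. The row labelled Gmnn was at 0.36 (0.04 to 0.69), but at -0.66 with equal weight for each cell and at -0.38 at equal depth. The row labelled Cdt1 was at -0.97 (-1.16 to -0.78), Hlf at -0.88 (-1.20 to -0.58), Mecom at -2.72 (-4.75 to -1.57) and Slamf1 at -0.43 (-0.75 to -0.11). The row labelled Mecom had only 5 counts in 4 mAG+ cells and 23 in 3 mKO2neg cells, and was at -0.64 at equal depth. The row labelled Ccnd3 was higher in mAG+, at 1.47 (0.38 to 2.98), which was 0.69 at equal depth. It had 36 counts in 9 mAG+ cells and 7 in 4 mKO2neg cells. Of 17 measured rows with G2/M labels, 6 were higher and 11 lower in mAG+, with a median of -0.35 (-0.69 to -0.09). This direction turned to 0.03 with equal weight for each cell, to 0.05 without the filter on low counts and to 0.09 without the deepest cell of each gate. With the counts of the preceding gene, taken up in the closing section, the G2/M median was 3.11 (2.98 to 3.25), with 54 of 54 rows higher in mAG+. The S phase list had a median of -0.10 (-0.27 to 0.13), with 10 of 22 rows higher, and was at 0.15 at equal depth. The stem cell list had 7 of 11 rows lower in mAG+ and a median of -0.88 (-1.12 to -0.36). At equal depth per cell, over the rows that still had at least 10 counts, this median was 0.07. Rows with lymphoid progenitor labels had a median of 1.64 (1.26 to 2.30), with 4 of 5 higher, and rows with MHC class I labels 0.72 (0.37 to 1.09), with 3 of 4 higher but a summed CPM of 723 against 694. With equal weight for each cell the lymphoid progenitor median was 0.75. With the counts of the preceding gene the MHC class I median changed sign.

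**Figure D2:**
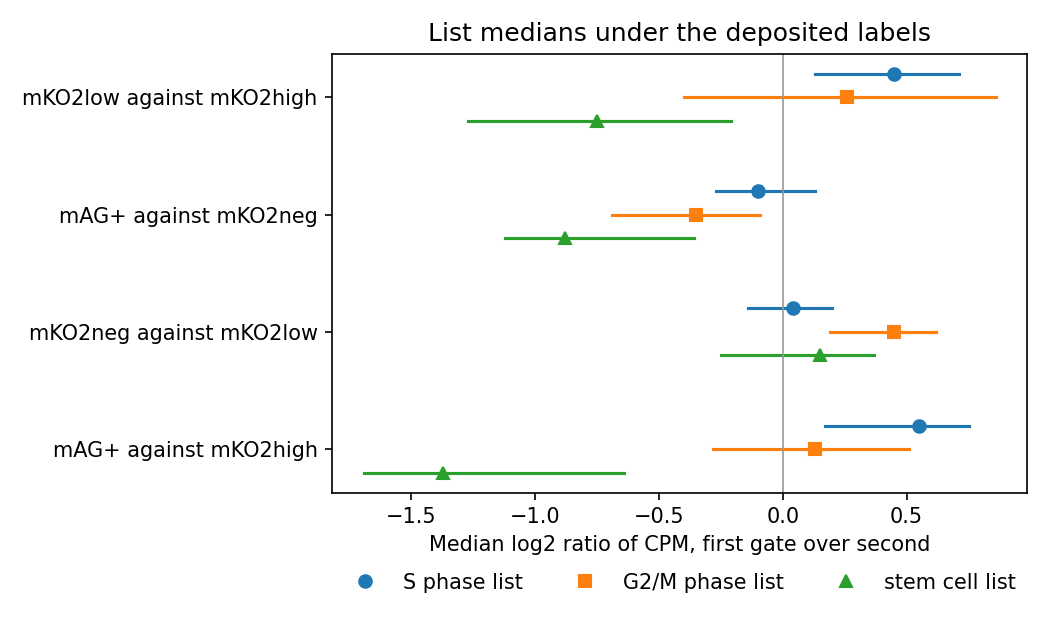
Median log2 ratio of CPM (horizontal axis) of the rows labelled with S phase, G2/M phase and stem cell genes in each comparison of gates (vertical axis), with lines for the 95% counting interval. The stem cell medians are -0.75 for mKO2low against mKO2high and -0.88 for mAG+ against mKO2neg. At equal depth per cell, over fewer rows, both medians lay above these intervals. Labels and counts were at odds, so these are not values of the stem cell genes themselves.

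The other comparisons set gates of different libraries side by side, so that gate and library cannot be told apart. In mKO2neg against mKO2low, rows with interferon response labels were lower in 7 of 8 cases, with a median log2 ratio of -1.91 (-2.57 to -1.45). Rows with TGF beta target labels were higher in 5 of 6, with a median of 1.30 (0.68 to 1.81) but a summed CPM of 252 against 249.5. At equal depth these medians were -0.48 and 0.73. The G2/M list had a median of 0.45 (0.19 to 0.62), which was -0.08 with equal weight for each cell. The S phase median was 0.04 (-0.14 to 0.20) and the stem cell median 0.15 (-0.25 to 0.37), which was -0.44 at equal depth. The row labelled Hlf was at 0.38 (0.06 to 0.71), that labelled Cdt1 at 0.21 (0.03 to 0.40) and that labelled Gmnn at 0.29 (-0.10 to 0.70).

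In mAG+ against mKO2high, the ends of the reporter order, 9 of 10 rows with stem cell labels were lower in mAG+, with a median of -1.37 (-1.69 to -0.64), below all but 0.0200% of matched random lists. The row labelled Hlf was at -2.14 (-2.44 to -1.86), that labelled Mecom at -3.81 (-5.89 to -2.78) and that labelled Cdt1 at -1.12 (-1.34 to -0.92). At equal depth the row labelled Hlf was at -0.65. That labelled Mecom was at 0.87, a value resting on too few counts to show a direction. The row labelled Mecom had only 5 counts in 4 mAG+ cells and 30 in 5 mKO2high cells. The S phase list had a median of 0.55 (0.17 to 0.75), with 12 of 18 rows higher, and the G2/M list 0.13 (-0.28 to 0.51), with 9 of 17 higher. The G2/M median rose above this interval without the filter on low counts and with the counts of the preceding gene. Rows with antioxidant labels had a median of -0.73 (-0.94 to -0.27) and rows with interferon response labels -1.12 (-1.52 to -0.51). The antioxidant median changed sign with the counts of the preceding gene. Higher in mAG+ were rows with lymphoid progenitor labels, with 4 of 5 higher and a median of 3.01 (2.36 to 4.30). This median was 1.88 with rows without counts in 1 gate at the floor, and fell below its interval with the largest cell of each row left out. Rows with oxidative phosphorylation labels were also higher, 14 of 20, with a median of 0.69 (0.36 to 0.87). At equal depth the S phase median was 0.11, the stem cell median -0.44, the interferon response median -0.21 and the oxidative phosphorylation median 0.24.

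The share of cells with counts in at least 5 rows labelled with G2/M genes was 22.9% in mKO2high (11 of 48, 95% interval 12 to 37.3), 66.7% in mKO2low (32 of 48, 51.6 to 79.6), 41.7% in mKO2neg (20 of 48, 27.6 to 56.8) and 79.2% in mAG+ (38 of 48, 65.0 to 89.5). At equal depth the shares were 2.56% of 39 mKO2high cells (0.0649 to 13.5), 6.25% of 48 mKO2low cells (1.31 to 17.2), 11.6% of 43 mKO2neg cells (3.89 to 25.1) and 15.6% of 45 mAG+ cells (6.49 to 29.5), with overlapping intervals. With at least 3 rows at equal depth the order differed, at 35.9% in mKO2high, 56.2% in mKO2low, 58.1% in mKO2neg and 48.9% in mAG+. Rows with G2/M labels held a median of 0.0562% of a cell's counts in mKO2high, 0.0956% in mKO2low, 0.0763% in mKO2neg and 0.0818% in mAG+.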

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

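Of 156 alternative values of list medians, gene rows per cell and shares of cells, 117 moved by less than the counting interval or the spread over cells. Some alternatives could hardly move a value. The TMM factors were 0.987 to 1.01, the size factors followed the gate totals, and the mitochondrial share was alike in all gates. Counts of values that stayed, here and for named rows below, are therefore no measure of how stable a value is. Of 132 alternative medians of the S phase, G2/M and stem cell lists, 18 changed sign, 7 of them where the interval of the reported value excluded 0 and 11 where it did not. Causes were not tested, except that thinning leaves fewer measured rows. At equal depth per cell, the S phase median was -0.15 for mKO2low against mKO2high, 0.15 for mAG+ against mKO2neg and 0.11 for mAG+ against mKO2high. The stem cell median was then -0.07, 0.07 and -0.44, and for mKO2neg against mKO2low it was -0.44, with a G2/M median of 0.14. With equal weight for each cell, the G2/M median was 0.03 for mAG+ against mKO2neg and -0.08 for mKO2neg against mKO2low, and the S phase median of mAG+ against mKO2high 0.06. Without the filter on low counts, the G2/M median was 0.05 for mAG+ against mKO2neg and 0.65 for mAG+ against mKO2high, and the stem cell median of mKO2neg against mKO2low 0.38. With the largest cell of each row left out, the S phase median of mAG+ against mKO2neg was 0.28.

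Chosen after the data were seen, leaving out the deepest cell of each gate gave a stem cell median of -1.28 for mKO2low against mKO2high and a G2/M median of 0.09 for mAG+ against mKO2neg. The counts of the preceding gene in annotation order, also chosen then, gave S phase medians of 1.21, 0.97, 0.24 and 2.68 in the order of the report's comparisons, G2/M medians of 0.67, 3.11, 0.97 and 5.20, and stem cell medians of -0.44, -0.34, -0.14 and -0.81.

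The other lists in the report had 130 alternative medians, of which 106 stayed within the counting interval and 2 changed sign, both with the counts of the preceding gene. These were MHC class I for mAG+ against mKO2neg, at -0.18, and antioxidant for mAG+ against mKO2high, at 0.03. With the largest cell of each row left out, the lymphoid progenitor median of mAG+ against mKO2high was 1.11 and the interferon response median of mKO2low against mKO2high 0.10. The lymphoid progenitor medians had no value at equal depth, where no listed row reached 10 counts.

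At equal depth, gene rows per cell were 1888 in mKO2low and 2138 in mAG+, and the G2/M shares 2.56%, 6.25%, 11.6% and 15.6% in mKO2high, mKO2low, mKO2neg and mAG+. At the deposited depth, the shares with at least 3 listed rows were 60.4%, 87.5%, 85.4% and 89.6%, and with at least 10 they were 0% (0 of 48, which allows up to 7.40%), 4.17%, 2.08% and 8.33%. Of 568 values of named rows, 507 stayed within the counting interval and 13 changed sign, 7 of them where the interval of the reported value excluded 0 and 6 where it did not. At equal depth, the row labelled Mecom was at 0.41 against mKO2high in mKO2low and at 0.87 in mAG+, Gmnn at -0.38 for mAG+ against mKO2neg, and Ccnd3 and Flt3 at 0.11 and 1.04 for mKO2neg against mKO2low. As deposited, the row labelled Flt3 had 1 count in mKO2neg and 9 in 1 mKO2low cell, so its value shows no direction. The rows labelled Mecom and Ccnd3 were sparse as well. With equal weight for each cell, the row labelled Gmnn was at -0.66 for mAG+ against mKO2neg and at -0.15 against mKO2high. No paired analysis was possible because each gate is 1 sample, and no replicate could be left out. The values were counts, so the pseudocount for normalized values was not run.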

Other observations

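The tests on displaced labels, strand and build were chosen only after the result was seen. Thinning to equal depth was planned, but the bounds of the depth test were set after its result was seen, and those of the tests on single cells and on the top rows before. Rows labelled with genes that most cells transcribe were almost empty, while rows next to them held many counts. A candidate explanation is that each count stands under the ID of the gene that precedes its own in the annotation's order. With the counts of the preceding gene, the 83 ribosomal protein genes as a group would hold 19.9% of all counts, against 0.167% as deposited and at most 0.473% at any of the other offsets from -5 to 5. Protein-coding genes as a group would then hold 92.6% of all counts, against 51.9% as deposited and at most 53.1% at the other offsets. Counting on the wrong strand was argued against, since 44 of the 200 labels with most counts overlap a protein-coding gene on the opposite strand. A different genome build was argued against as well, because an offset of exactly 1 gene gave the highest ribosomal protein total on 19 of 19 chromosomes.

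The G2/M list was not higher in mAG+ than in mKO2neg under the deposited labels, although mAG marks S, G2 and M cells. With the counts of the preceding gene, its median log2 ratio would be 3.11 (2.98 to 3.25), with 54 of 54 rows higher in mAG+, which is consistent with displaced labels. Leaving out the cell with most counts per row and gate gave a median of -0.17 (-0.49 to 0.15). That argues against single cells hiding a rise above this interval. The interval includes 0, unlike that of the reported median of -0.35 (-0.69 to -0.09), so the test does not decide whether single cells made the median negative. The cause of a displacement was not tested, and these list totals give no row another name. The tables with their row names as first written by the study would settle it.

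The mAG+ cells had more gene rows counted than mKO2neg cells, a pattern that uses no gene name. Deeper sequencing as the whole cause was argued against, since at equal depth the mAG+ median was still 15.6% above that of mKO2neg. At that depth the 100 rows with most counts of a cell held a median of 34.2% of the counts in mKO2neg and 30.8% in mAG+, a difference of 3.40 percentage points, under the 5 points set in advance for a few rows as the cause. The cell cycle difference that the gates were sorted on may underlie the pattern and stays open as untested, as does any difference in handling between the gates.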
